A study of Oryza sativa with 6 samples.

How the data were processed

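Total RNA from leaves was extracted with Trizol, and biotin-labelled cRNA was made from 6 µg of it by the standard Affymetrix procedure, per the labels' protocols. Seeds germinated at 28 °C for 2 days, and seedlings grew under 16 h light at 30 °C and 8 h dark at 26 °C, per the labels. The samples are 6 arrays, 3 of KMD and 3 of XS11, grouped by their titles.

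The deposited values are microarray intensity on a linear scale, 1 value per probe set and array, in 1 table for the series. The submitters' processing notes name MAS5, and its version, the scaling target and any later normalization are not given in the sources used here. The minimum was 1 and the highest maximum 16460. Trimmed mean intensities lay between 136 and 138 in KMD and between 141 and 142 in XS11, so the arrays had been brought to a similar but not equal level. Scanner files and detection calls were not analysed here. All 6 columns of values were used.

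The table held 57381 probe sets, of which 123 were control probe sets and 64 reporter probe sets. Gene names came from a platform annotation and from the symbols and synonyms of the RefSeq table of assembly ASM3414082v1. In the annotation 22436 probe sets had 1 gene, 95 had several and were not named, and 34850 had no gene and are unnamed here. The 17905 different genes were all found by gene ID in the RefSeq table, and 2454 had an informative symbol. No genome build is named for the deposited values, so no positions are given, and the assembly served only for names and for which genes neighbour each other.

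The signal was transformed as log2(signal + 11.17), where 11.17 is the 10th percentile of all values, with no further normalization. Fold changes are on this scale, which understates the change of dim probe sets. Probe sets in the upper 60% of mean log2 signal were tested, together with all reporter probe sets, and control probe sets were left out, which gave 34404 tests. KMD was compared with XS11 by limma (lmFit, eBayes with an intensity trend, two-sided) with Benjamini-Hochberg adjustment and a threshold of 0.05. The replicate numbers were not used as a block. On data simulated from the real means and spreads for this comparison, with 34404 probe sets, the fit recovered 68.7%, 98.5% and 100% of changes of 0.5, 1 and 2 on the log2 scale and called 0.0263% of unchanged probe sets. Only 67, 67 and 66 probe sets were changed in that simulation, while 39.7% of the tested probe sets were called in the real comparison. The adjusted threshold loosens as more probe sets differ, so these shares do not carry over to the real calls.

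Gene lists were tested with limma's camera at a preset correlation of 0.01, with 1 probe set per gene (the brightest) and at least 5 tested genes per list. Of 35 lists fixed before the data were examined, 12 matched genes on the array and 3 were large enough, because the naming tables hold no gene descriptions. For that reason 44 lists of gene symbols were added after the naming table and the control and reporter values had been seen. On simulated data camera recovered the 1 shifted list and also called 2 unshifted ones, of which the heat shock list fixed beforehand shares genes with it and the WRKY list is a false call.

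Genes named in the text were chosen by a rule fixed before the data were examined. In each direction it takes the 12 probe sets with the largest absolute log2 fold change among those past the adjusted threshold, with no overlap between the lines, exactly 1 gene and an informative description, 1 probe set per gene. As no descriptions were at hand, an informative symbol or synonym stood in for the description. The rule also takes every reporter probe set past the threshold and up to 4 members of each list, those past the threshold by size of change. Where a gene is given with its list, its value is that of its brightest probe set.

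The alternatives tried were pseudocounts of 1 and of the 25th percentile (18.5), no filter or the upper 40% of signal, quantile normalization, median centring, eBayes without the trend, array weights, the replicate number as a block, leaving out each array, an estimated correlation, fry, and all probe sets of a gene. Added after seeing the data were centring on the poly-A spike-ins and a limma test against a change of 1.2-fold. Positions of changed genes were tested with 1000 permutations of the calls among the placed genes, and intervals of shares are exact 95% binomial intervals. The tools were R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.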

Results

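The series measured mRNA levels in leaves of 30-day rice seedlings. Per the labels, it set the transgenic line KMD against its parent, the cultivar Xiushui 11 (XS11), with 3 arrays of each line. KMD is known as a Bt rice that carries a cry1Ab gene of Bacillus thuringiensis, which the labels do not state. The stated question was which genes differ between the lines, as a lead on unintended effects of the transformation. The value table held 57381 probe sets of the Affymetrix rice array for each of the 6 arrays. Median intensities per array ran from 35.5 to 38.7. Across the tested probe sets, the log2 signals of arrays from the same line correlated at 0.995 to 0.997, and those of arrays from different lines at 0.974 to 0.976.

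Of the array's 64 reporter probe sets, which stand for sequences common in plant transformation, 3 were bright in every KMD array and near the dim end of the scale in every XS11 array. RPTR-Os-A06498-1_at read 4334 ± 88.6 in KMD and 12.9 ± 4.73 in XS11 (mean ± SD, n = 3 each), a log2 difference of 7.51 (SE 0.10). RPTR-Os-K01193-1_at read 2343 ± 42.0 against 11.2 ± 0.61, a log2 difference of 6.71 (SE 0.05). RPTR-Os-A00196-1_s_at read 1684 ± 67.3 against 16.5 ± 0.79, a log2 difference of 5.93 (SE 0.05). RPTR-Os-X17220-1_at went the other way, at 12.6 ± 2.78 in KMD and 62.0 ± 0.85 in XS11 (log2 difference -1.63, SE 0.10).

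In all, 7 of the 64 reporter probe sets passed the limma test with Benjamini-Hochberg adjustment over all tested probe sets, and 6 passed when adjusted over the list alone. The adjusted p of RPTR-Os-A06498-1_at was 1.23e-14 in limma, and that of RPTR-Os-X17220-1_at was 1.93e-08. RPTR-Os-U89963-1_at (-0.32), RPTR-Os-U89963-1_x_at (-0.31) and RPTR-Os-AF292560-1_s_at (0.22) differed by small amounts. The last of these read 9.07 in KMD and 6.17 in XS11 (means of 3 arrays), both under the 10th percentile of all values (11.17), so it is not shown to be above background. It has a limma adjusted p of 0.048, lost without KMD replicate 1 (log2 difference 0.18), KMD replicate 3 (0.24), XS11 replicate 1 (0.25), XS11 replicate 2 (0.18) or XS11 replicate 3 (0.24). RPTR-Os-U89963-1_at was lost without KMD replicate 3 or XS11 replicate 1, and RPTR-Os-U89963-1_x_at without KMD replicate 1. Over the settings fixed beforehand, 5 to 9 reporter probe sets were called. The count was 6 with the pseudocount of the 25th percentile, with no filter and in the upper 40% of signal. The tables used here do not give the transgenes behind these probe sets.

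**Figure D1:**
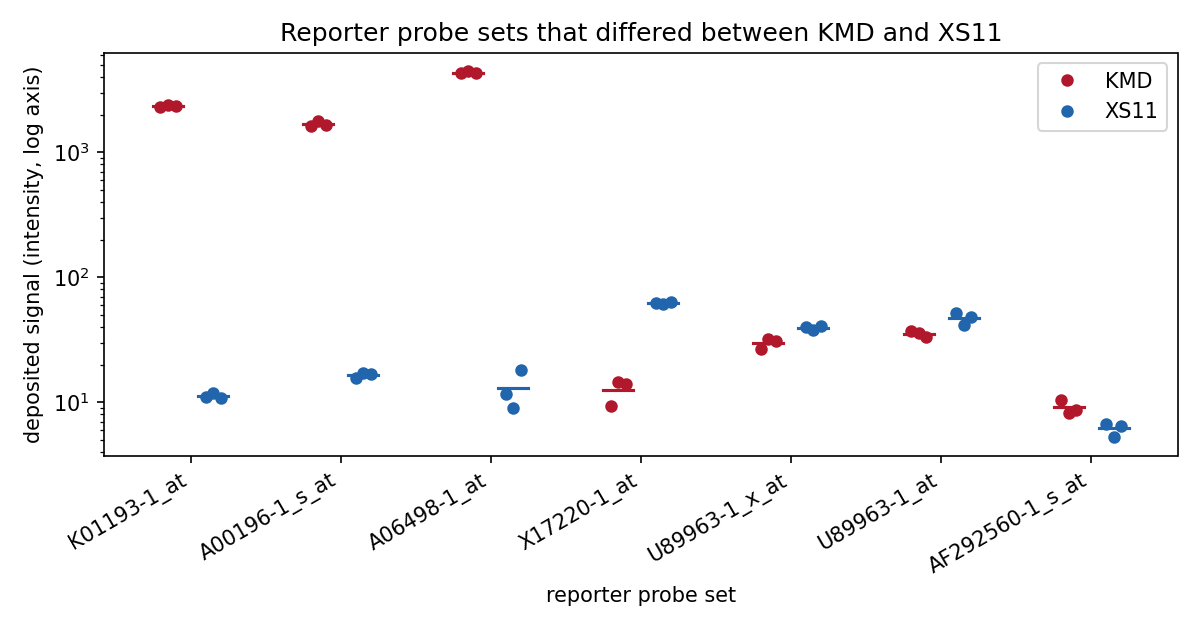
Deposited intensity (log axis) of the 7 reporter probe sets past the test, named without their shared prefix. Points are single arrays, 3 KMD (red) and 3 XS11 (blue), and short lines are group means: A06498-1_at, K01193-1_at and A00196-1_s_at stand at 4334, 2343 and 1684 in KMD and at 12.9, 11.2 and 16.5 in XS11.

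Among rice genes with a name, the largest rises in KMD were in ARD1 and METK3. ARD1, an acireductone dioxygenase of the methionine salvage cycle, rose from 54.3 ± 1.64 to 597 ± 16.8 (SD, n = 3 each), which is 9.28-fold on the log2(signal + 11.17) scale (log2 fold change 3.21, SE 0.05). METK3, named as an S-adenosylmethionine synthase, rose from 30.8 ± 4.33 to 337 ± 3.71 (log2 fold change 3.06, SE 0.08). The largest falls were in the CCCH zinc finger gene OsC3H40, from 725 ± 9.40 to 18 ± 1.85 (log2 fold change -4.66, SE 0.06), and in the 4-coumarate:CoA ligase-like gene 4CLL7, from 743 ± 8.73 to 32.7 ± 3.42 (log2 fold change -4.11, SE 0.06).

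The other 10 genes named for a rise covered several functions. BURP2, of the BURP domain family, rose by a log2 fold change of 2.64 (SE 0.06). GRXC15, a glutaredoxin, rose by 2.24 and the calcineurin B-like interacting kinase CIPK14 by 1.78. CAD8C, of the cinnamyl alcohol dehydrogenase family that acts in lignin synthesis, rose by 1.56. XRT5, also listed as the xyloglucan-modifying enzyme XTH8, rose by 1.51. ABA8OX1, an abscisic acid 8'-hydroxylase that breaks down abscisic acid, rose by 1.40. ILL8, an IAA-amino acid hydrolase-like gene, rose by 1.31, the calmodulin-like CML31 by 1.27, the zinc finger gene SAP17 by 1.26 and the LSD1-like zinc finger gene LOL4 by 1.23. The standard errors of these 10 log2 fold changes are drawn in the plot of the largest changes.

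Among the other 10 genes named for a fall, AT5 fell by 2.37 on the log2 scale (SE 0.05) and ASMT1, an N-acetylserotonin methyltransferase of melatonin synthesis, also fell by 2.37 (SE 0.10). CYP71P1, the tryptamine 5-hydroxylase that makes serotonin, fell by 1.94. Transporters were among them: the ammonium transporter AMT3-2 fell by 1.95, the aquaporin NIP1-1 by 1.80 and the potassium transporter HAK1 by 1.75. ADF-11, an actin-depolymerizing factor and the brightest of the 24 genes, fell from 5296 ± 77.8 to 1595 ± 58.8 (log2 fold change -1.73). CPS4, a diterpene cyclase of momilactone phytoalexin synthesis, fell by 1.72, the metallothionein MT2C by 1.71 and the MADS-box gene FDRMADS3 by 1.69. In limma with Benjamini-Hochberg adjustment, the 24 genes ran from an adjusted p of 1.54e-14 for OsC3H40 to 7.18e-08 for SAP17.

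Among these genes, only ARD1, BURP2, HAK1 and MT2C had other tested probe sets. Each of the rest, METK3, OsC3H40 and 4CLL7 included, rests on 1 tested probe set. A second probe set of ARD1 gave a log2 fold change of -0.07 (adjusted p = 0.61 in limma), so the rise of ARD1 rests on 1 of its 2 probe sets. The other probe set of BURP2 rose by 0.84, less than the first. All 5 probe sets of MT2C fell, by 1.36 to 1.71, and both of HAK1 fell, by 1.35 and 1.75. Probe sets of the types a_at, s_at and x_at, such as those read for BURP2, CIPK14, AMT3-2, HAK1, CPS4 and MT2C, can take signal from other transcripts of the gene or from related genes.

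**Figure D2:**
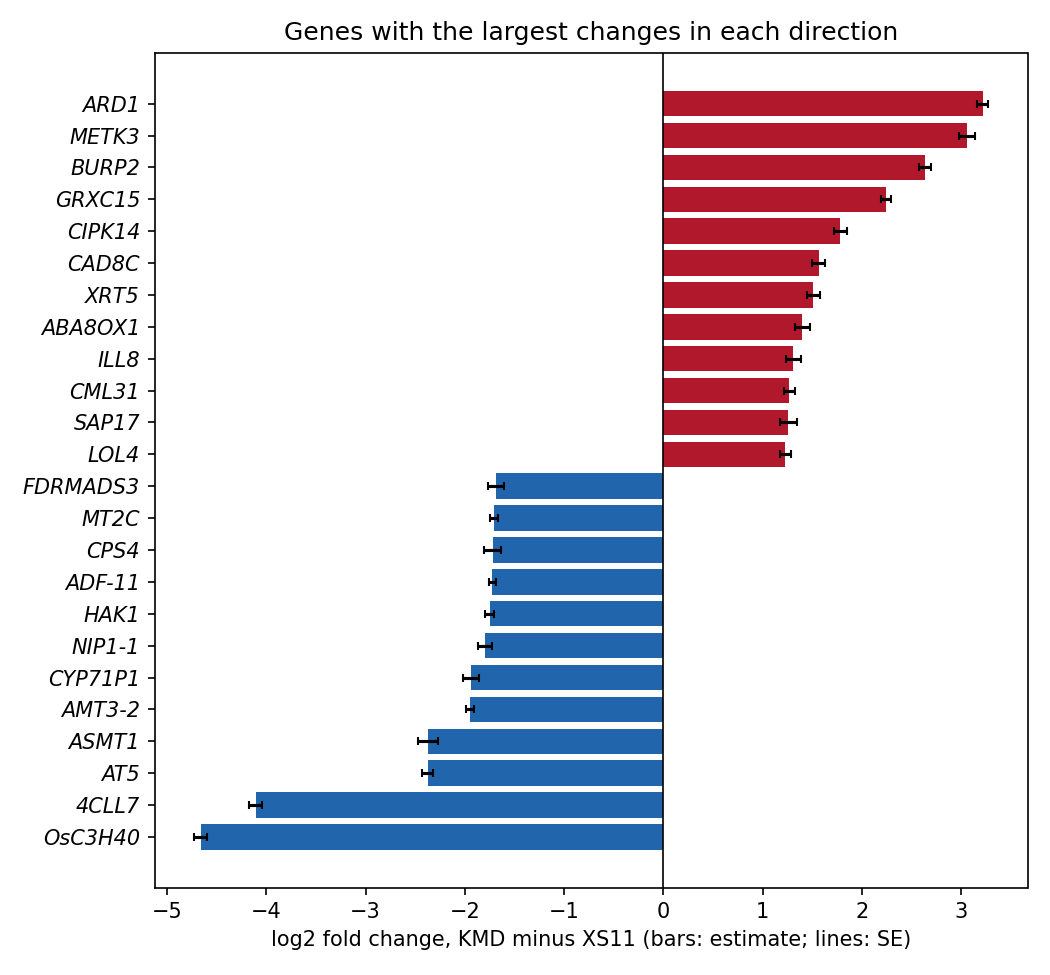
Log2 fold change, KMD minus XS11, of the 12 named genes with the largest change in each direction, from 3 arrays per line. Bars are the limma estimates and black lines the standard errors: the values run from 3.21 for ARD1 to -4.66 for OsC3H40.

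Over all 34404 tested probe sets, 13660 (39.7%) differed between the lines, 6222 higher and 7438 lower in KMD. Most of these differences were small, with a median absolute log2 fold change of 0.33. At least 2-fold changes numbered 613, with 197 higher and 416 lower, and at least 4-fold changes 61 higher and 49 lower. The 613 probe sets held 380 different genes, of which 75 had an informative symbol. Of all tested probe sets, 48.8% showed no overlap between the arrays of the lines, against 10% by chance. A test against a change of 1.2-fold, chosen after seeing the data, left 4102 probe sets, 1535 higher and 2567 lower.

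All these changes are relative to the overall level of each array, and control transcripts showed that this reference matters. The 36 probe sets of the poly-A spike-ins were all higher in KMD, by 0.62 on average on the log2 scale, while the array-wide median log2 fold change was 0.0017. Centring on these spike-ins, chosen after seeing the data, moved the median to -0.63 and the calls to 307 higher and 32726 lower. On that scale a gene that rose by less than 0.63 in the values used here is lower in KMD. The ratio of 3' to 5' signal, a sign of RNA integrity and labelling, was 5.79 ± 0.14 in KMD and 4.62 ± 0.30 in XS11 for actin (SD, n = 3 each). For GAPDH it was 3.48 ± 0.05 and 2.75 ± 0.21, for ubiquitin 1.17 ± 0.02 and 0.99 ± 0.03, and for cyclophilin 0.91 ± 0.06 and 1.06 ± 0.05.

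**Figure D3:**
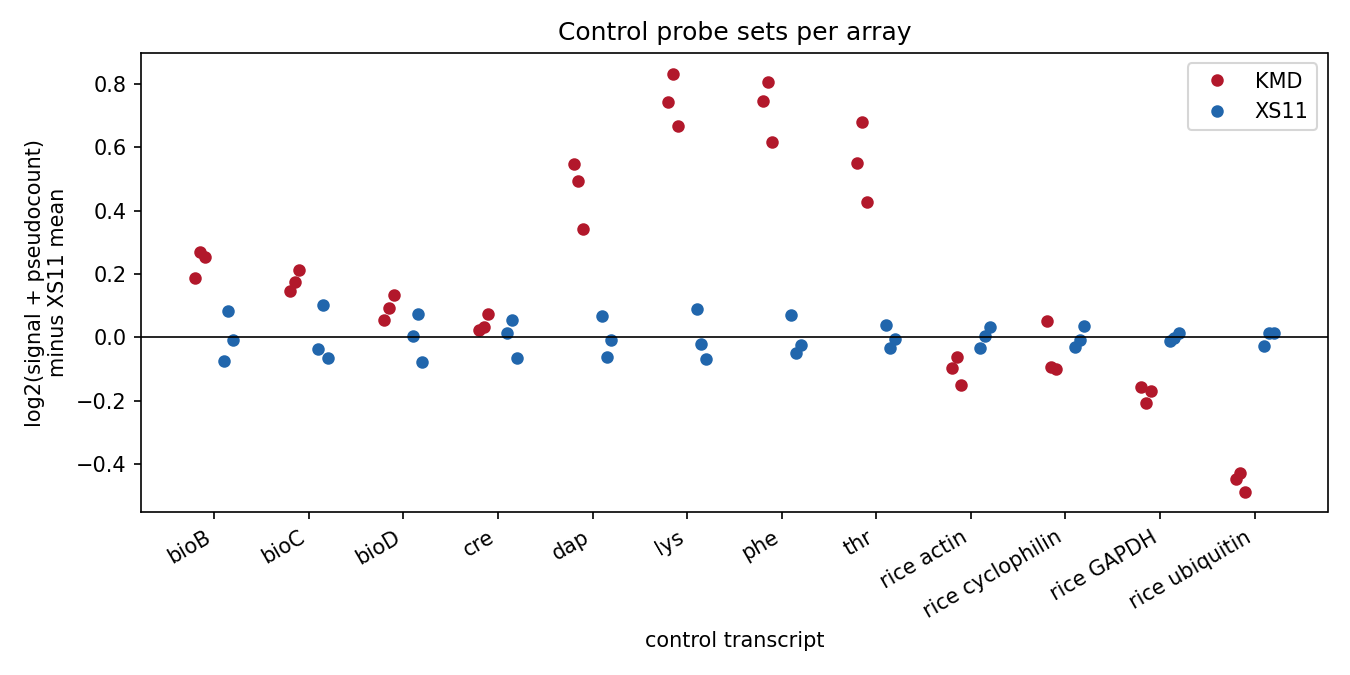
Mean log2(signal + 11.17) of control transcripts in each array minus the mean of the 3 XS11 arrays. Points are single arrays of KMD (red) and XS11 (blue): the poly-A spike-ins dap, lys, phe and thr lie 0.46 to 0.75 higher in KMD, bioB and bioC 0.24 and 0.18 higher, and rice ubiquitin at -0.45.

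Of the gene lists fixed before the data were examined, 3 had enough measured genes to test, and limma's camera called 0 of them (1 at an unadjusted p under 0.05; fry, which tests for movement in 1 direction on balance, called 3). The iron acquisition and storage list had 12 tested genes, of which 0 rose, 6 fell and 6 did not pass (7 passed when adjusted over the list alone). Its metal-chelate transporters YSL13 (log2 fold change -1.05), YSL12 (-1.04) and YSL16 (-0.68) fell, and the list as a whole had a camera adjusted p of 0.105. Of 19 heat shock genes, 5 rose and 9 fell (14 passed when adjusted over the list alone), with HSP16.0 at 0.96 and HSP81-3 at -0.88 (camera adjusted p = 0.389). Other tested probe sets of HSP81-3 gave -1.275, -0.91 and -0.02 (adjusted p = 0.89 in limma for the last). Of 6 WRKY transcription factor genes, 3 rose and 2 fell (5 passed when adjusted over the list alone), with WRKY24 at 0.97 (camera adjusted p = 0.389).

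A further 44 lists, made from gene symbols after the naming table and the control and reporter values had been seen, those of rice control genes included, gave 14 calls by camera with its preset correlation of 0.01, 13 of them lower in KMD. None of the 14 was kept with an estimated correlation, where 4 of the 44 lists had an unadjusted p under 0.05, while fry called 35. Other splits of the 6 arrays, which mix the lines, gave up to 6 such calls, but each of them still sets more KMD arrays against more XS11 arrays, so these counts do not measure false calls. The counts of single genes in the lists come from limma, and the 3' to 5' ratios given above differed between the same arrays. These counts use the brightest probe set of each gene. In the upper 40% of signal, 12332 of 22963 probe sets were called, 5596 higher and 6736 lower. Of 14788 placed genes, also read by their brightest probe set, 90 were at least 2-fold higher and 268 lower. That threshold is stricter than that of the list counts, which take called changes of any size. Genes at large thus also leaned lower in these values, so a count that leans lower is not by itself particular to its list. Quantile normalization turned this lean over all called probe sets, to 7213 higher and 6757 lower. At 2-fold or more the lean stayed, with 209 higher and 384 lower. The 13 lists called lower kept negative medians after quantile normalization. On the spike-in scale the median of every one of the 44 lists was lower in KMD, and camera called 10. The 14 lists share some genes.

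Among the called lists, 3 hold genes of the plant cell wall. Of 24 phenylpropanoid and lignin genes, 1 rose, 19 fell and 4 did not pass; CAD2 fell by 1.35, 4CL-3 by 1.22 and HCT2 by 0.95, while CAD8C rose (camera adjusted p = 0.00017; adjusted p = 0.21 with an estimated correlation). Of 38 cellulose synthase and related wall genes, 2 rose, 28 fell and 8 did not pass (camera adjusted p = 0.00025, and 0.32 with an estimated correlation). CESA3 (-1.37), TBL11 (-1.08) and CESA1 (-1.03) fell most, while XRT5 rose by 1.51. CESA1 and CESA3 encode cellulose synthase subunits. Of 16 expansin genes, whose products loosen the wall, 0 rose, 8 fell and 8 did not pass, with EXP2 at -0.92 and EXPB4 at -0.90 (camera adjusted p = 0.032; adjusted p = 0.44 with an estimated correlation). The expansin call was lost without XS11 replicate 3 (adjusted p = 0.072).

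Other called lists hold transport genes. Of 23 aquaporin genes, 1 rose, 18 fell and 4 did not pass, with NIP1-1 at -1.80, TIP4-1 at -1.29 and PIP2-5 at -1.03 (camera adjusted p = 0.00018; adjusted p = 0.21 with an estimated correlation). Of 23 potassium and sodium transport genes, 3 rose, 14 fell and 6 did not pass, with HAK1 at -1.75, the potassium channel KCO1 at -1.21 and HAK27 at -1.11 (camera adjusted p = 0.020; adjusted p = 0.32 with an estimated correlation). Of 20 nitrogen uptake and assimilation genes, 1 rose, 11 fell and 8 did not pass, with AMT3-2 at -1.95, the nitrate uptake partner NAR2.2 at -1.26 and AMT3-3 at -1.10 (camera adjusted p = 0.012; adjusted p = 0.32 with an estimated correlation). Of 11 ABC transporter genes, 1 rose and 7 fell, with ABCG48 at -0.89 (camera adjusted p = 0.022; adjusted p = 0.32 with an estimated correlation). The phosphate list was not called: of 16 genes 2 rose, 8 fell and 6 did not pass, with PHT1-2 at -1.19 (camera adjusted p = 0.218).

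Of the lists of defence and hormone genes, some were called and others were not. Of 20 diterpenoid synthesis genes, 4 rose, 13 fell and 3 did not pass, and the phytoalexin genes CPS4 (-1.72), CYP76M7 (-1.63) and CPS2 (-1.17) fell, as did KS10 (-1.19) (camera adjusted p = 0.020; adjusted p = 0.32 with an estimated correlation). Of 33 jasmonate genes, 3 rose, 19 fell and 11 did not pass, with the listed OPR-1 at -1.62, the repressor gene JAZ11 at -1.54 and the lipoxygenase gene CM-LOX2 at -1.21 (camera adjusted p = 0.012; adjusted p = 0.32 with an estimated correlation). Of 10 chitinase and pathogenesis-related genes, 0 rose, 7 fell and 3 did not pass, with Cht2 at -1.03 and PBZ1 at -0.94 (camera adjusted p = 0.020; adjusted p = 0.32 with an estimated correlation). Of 53 auxin genes, 7 rose, 32 fell and 14 did not pass (camera adjusted p = 0.015, and 0.44 with an estimated correlation). IAA31 fell by 1.06 and IAA21 by 0.94, while ILL8 rose. The other tested probe set of IAA31 gave -0.14 (adjusted p = 0.197 in limma). Of 26 abscisic acid and drought genes, 3 rose, 15 fell and 8 did not pass, with the late embryogenesis abundant gene LEA19 at -1.34 (camera adjusted p = 0.020; adjusted p = 0.32 with an estimated correlation). Lists not called were immune signalling (35 genes, 9 rose and 11 fell, camera adjusted p = 0.932), cytokinin (28 genes, 6 rose and 11 fell, 0.927) and ethylene (16 genes, 1 rose and 4 fell, 0.491).

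The list of reference genes was written after the array's rice ubiquitin, GAPDH and actin controls had been seen lower in KMD, so it is no separate finding. Of its 23 ubiquitin, actin, tubulin and GAPDH genes, 1 rose, 16 fell and 6 did not pass, with AC7 at -0.57 and TUBA1 at -0.58 (camera adjusted p = 0.0097; adjusted p = 0.44 with an estimated correlation). The 1 called list that was higher in KMD held 21 glutathione transferase and glutaredoxin genes, of which 10 rose, 4 fell and 7 did not pass (camera adjusted p = 0.032; adjusted p = 0.44 with an estimated correlation). On the spike-in scale this list turned, with 1 of its 21 genes higher and 17 lower. GRXC15 led it at 2.24, GRXC7 went the other way at -1.49 and GRXC1 rose by 0.69. Of 11 genes on the root marker list 0 rose, 6 fell and 5 did not pass (camera adjusted p = 0.239, fry adjusted p = 0.00079). Lsi1 stood at -0.53, IRT1 at -0.51, HK3 at -0.37 and HK5 at -0.36. The list was matched by symbols and synonyms alone, so not every member is shown to be a root marker. Of 11 seed storage, pollen or anther genes 3 rose and 1 fell (camera adjusted p = 0.467). Of 11 light harvesting and photosystem genes, 2 rose and 4 fell, the largest change being -0.28 for LFNR1 (camera adjusted p = 0.939).

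**Figure D4:**
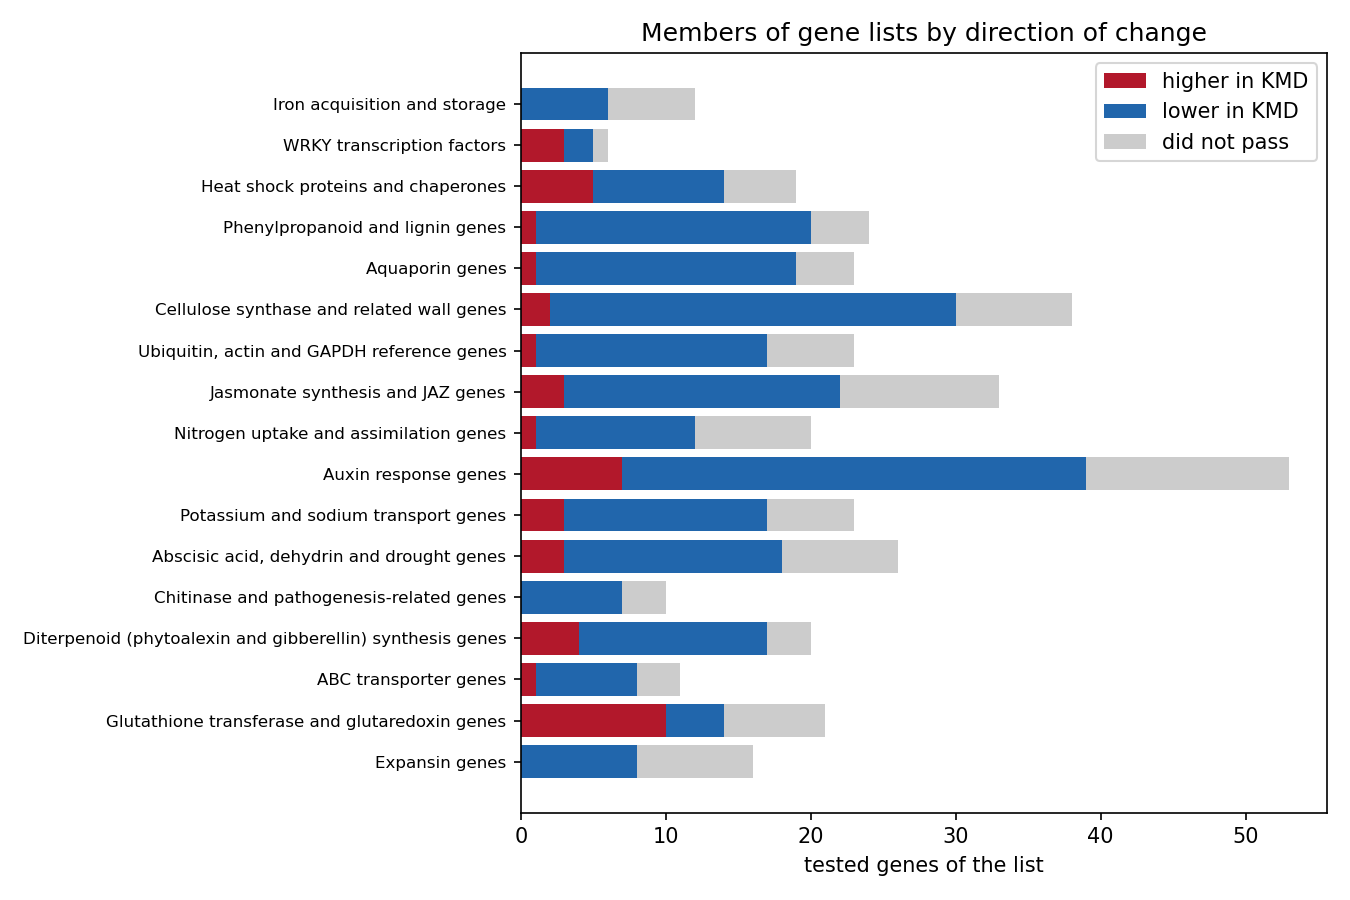
Number of tested genes per list that were higher (red) or lower (blue) in KMD at an adjusted p below 0.05 or did not pass (grey), for the 3 lists fixed before the data were examined (top) and the 14 symbol lists called by camera. Phenylpropanoid genes show 1 higher and 19 lower, and the glutathione transferase and glutaredoxin genes 10 higher and 4 lower.

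The number of arrays, 3 per line, limits the precision, and no batch or hybridization date is given in the sources used here, so any batch that followed the lines cannot be told apart from them. The labels call the samples biological replicates without saying how many plants each held.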

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

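Control transcripts, which were left out of the tests of single genes, differed between the lines, and 6 added ones were higher in every KMD array than in every XS11 array. The poly-A spike-ins, added to RNA before labelling, were higher in KMD by 0.46 (dap), 0.75 (lys), 0.72 (phe) and 0.55 (thr) on the log2 scale, with n = 3 arrays per line. The hybridization controls bioB and bioC, added after labelling, were higher by 0.24 and 0.18, while bioD (0.09) and cre (0.04) overlapped between the lines. The rice controls ubiquitin (-0.45), GAPDH (-0.18) and actin (-0.10) were lower in every KMD array than in every XS11 array. These shifts were not weighed further, and centring on the spike-ins gave 33033 calls.

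The test of 3' to 5' ratios, and the interval around the share of agreeing probe sets, were chosen only after the values were seen. For the small changes in many of the 13660 called probe sets, a global difference in scale between arrays was tested by quantile normalization. It left 13970 calls, 7213 higher and 6757 lower, so a difference that it removes does not account for their number. The balance of directions did turn, from 6222 higher and 7438 lower. The deposited arrays were already at a similar level, so little of that kind was left to remove. Quantile normalization does not test the reference itself, and centring on the poly-A spike-ins moved the calls to 307 higher and 32726 lower. Collection at different times of day was tested on LHY (log2 fold change -0.0342, SE 0.03) and PRR1 (-0.44, SE 0.06), clock genes that peak at opposite times, and both stayed under the bound of 0.58 set beforehand. That excludes opposite 2-fold shifts of this pair but not a smaller difference in time, since 8 of 15 clock and flowering-time genes fell and 1 rose, with PRR95 at -0.54 and GI at -0.42. A greater 3' bias of the labelled RNA in KMD stays open, since 3 of 4 rice control genes had a higher ratio in every KMD array. The ratio of cyclophilin (0.91 in KMD, 1.06 in XS11) was lower in every KMD array, which goes against a general bias. Such a bias cannot be told apart from the lines, because it would differ between the same arrays. The probes' places along the transcripts are not known here either. The difference between transgenic line and parent stays open as well, untested, and so does a batch.

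Changes of at least 4-fold, in 110 probe sets, may be in part effects on single probe sets, such as a sequence difference under the probes. In the 19 genes with other tested probe sets, 13 of 28 of those (46.4%) changed at least 2-fold in the same direction, and 22 had the same sign. A minority that changed so was the result set beforehand for effects on single probe sets, and this share meets it. The 95% interval of 27.5 to 66.1%, added after the values were seen, reaches from a minority to a majority. It treats probe sets of the same gene as independent and is therefore too narrow. With that interval, neither a change of the transcript nor an effect on single probe sets is settled for these genes. ARD1 is among those whose probe sets differ.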

How the results depend on the processing

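The settings named here as added, and the split test of the count of called probe sets, were chosen after seeing the data. The direction of every named gene was kept under all settings fixed beforehand, and the 24 genes with the largest changes among those with an informative symbol stayed past the threshold wherever they were tested; the calls that were lost, at most 8 of 191 named probe sets per setting, were all of changes of 0.32 or less on the log2 scale. Over these settings, the count of called probe sets ran from 11856 to 15361 and that at 2-fold or more from 517 to 762. Centring on the poly-A spike-ins (added) gave 33033 called probe sets, and 3517 at 2-fold or more (86 higher, 3431 lower), because it lowers KMD arrays as a whole. The test against a 1.2-fold change (added) gave 4102, since it asks for a larger change. With the replicate number as a block, 12450 probe sets were called and no list call changed. Deviations of same-numbered arrays correlated at -0.24, -0.01 and -0.25, so no positive shared deviation was seen. With 3 arrays per line, this does not settle whether same-numbered samples were handled together. Of the 3 lists fixed beforehand, 0 were called at first, 1 in the upper 40% of signal, 3 by fry and 3 with all probe sets of a gene; the cause was not tested, except that fry asks another question. Of the 44 symbol lists (added), 14 were called at first, 35 by fry and 0 with an estimated correlation, and adjusted p of the 14 then ran from 0.21 to 0.44. In the upper 40% of signal the calls of the abscisic acid (adjusted p = 0.061), ABC transporter (0.136) and diterpenoid (0.19) lists were lost, and with no filter those of the chitinase (0.064) and expansin lists. The expansin call was also lost with array weights, with all probe sets of a gene and without XS11 replicate 3. Of the 10 splits of the 6 arrays into 3 and 3, the real one gave 13660 calls and 613 at 2-fold or more, and the highest other 0 and 0 (limma; at most 1534 and 1 at an unadjusted p under 0.05). For both counts 1 split reached the real value, the real one. For the fixed lists all 10 splits gave at least the real 0, with 1 the highest other, and for the symbol lists 1 split reached the real 14, with 6 the highest other. With 10 splits the share cannot go under 0.1, and every other split keeps part of the difference between the lines. Dim signals limit the low end: values near 11.17 lie at the 10th percentile, where no detection call was used.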

Other observations

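Other genes with symbols also differed at least 2-fold, of which DUR3, SAM1, spdSyn1 and DMC1 were picked after their values were seen. LOGL9, of the family that activates cytokinins, fell by 1.64 on the log2 scale. The metallothionein MT1B fell by 1.60, the urea transporter gene DUR3 by 1.30 and the phosphate transporter gene PHT1-2 by 1.19. SAM1, which like METK3 is named as an S-adenosylmethionine synthase gene, fell by 1.22, and the spermidine synthase gene spdSyn1 rose by 1.18. DMC1, a recombinase gene of meiosis, rose by 1.09.

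The window counts with their 3 widths, the test of directions and the comparison of standard errors were chosen only after the result was seen. The test of neighbours was set beforehand, and the test of the window's other genes was set after the window was found but before their values were seen. Genes changed at least 2-fold were not spread evenly over the genome. Of 14788 genes placed by the RefSeq assembly ASM3414082v1, 358 were changed at least 2-fold, and 19 pairs of next neighbours changed in the same direction, against a median of 5 and a highest of 15 in 1000 permutations of the calls. That argues against random positions. A single stretch stood out: the best window of 100 successive array genes held 21 of the 358 (8 higher and 13 lower), against a highest of 13 in 1000 permutations and of 11 on other chromosomes. With windows of 50 and 200 array genes the counts were 13 and 27, against highest permuted counts of 10 and 19.

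That window runs through 4CLL7, ILL8, spdSyn1 and CESA3, and holds LOC4342989 (log2 fold change -4.39, from 412 ± 19.3 to 9.02 ± 2.45, SD, n = 3 each), LOC4342974 (3.30) and LOC4342894 (-3.08). A hypothesis is that a linked chromosomal segment differs between KMD and XS11, which could come with the transformation, with tissue culture or with a different seed parent. Its test was whether the other 79 genes of the window, those short of a 2-fold change, also moved more than elsewhere. Their median absolute log2 fold change was 0.30, above that of 100% of the 141 other windows (median 0.18, highest 0.25), while their median SE of 0.06 lay within the range of the other windows (0.05 to 0.07). Shared regulation of neighbours or tandem copies that cross-hybridise is not settled, since 38.1% of the changed genes went in the rarer direction (95% interval 18.1 to 61.6%), and no sequence data were analysed here.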
